A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

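Gene expression was measured in Schizosaccharomyces pombe with 1-colour NimbleGen arrays, in 4 strains with 2 arrays per strain, each array from a separate culture. Per the labels, pre-cultures were inoculated into 50 mL of YES medium and grown with rotation at 30 °C, and cells were taken after 8 hours, in logarithmic phase. Total RNA was converted to double-stranded cDNA and labelled with Cy3. The parent strain PR110 carries leu1-32 and ura4-D18, the latter a deletion of ura4. The other 3 strains are single disruptants of it, pka1::ura4, cgs1::ura4 and ppt1::kanMX6.

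The deposited values are intensity on a linear scale, per the file headers 1 gene-level summary of the probes of each array. The other columns hold, per the file headers, an error of each summary with no scale given and the number of probes, and no test used them. How the authors summarised the probes, and how far they normalized the arrays, is not given in the sources used here. The series value table was compared with the values of each array, and the largest difference was 0, so a fit on that table could change nothing. Of 4940 genes, 4922 had 14 probes and 18 had fewer. A control of random sequence was left out of the tests. Symbols came from a RefSeq table that pairs locus tags with symbols. It held 4913 of the genes, and 4147 genes had a symbol. Genes are named by that symbol, or by their systematic name. The files name no genome build, so no positions are given. Neighbouring genes were taken from the order of genes in the same table.

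Array medians lay between 21210 and 22148 in replicate 1 of all strains and between 24677 and 25548 in replicate 2, a mean difference of 0.22 on the log2 scale. The titles place all arrays of a replicate number on the same slide. For the 3 disruptants of slide 2, the array position in the title differs from that in the name of the deposited table. The strain given by the labels was used, and the signals of ura4, cgs1 and ppt1 on these arrays go with it. Deviations of arrays of the same slide from their strain means were correlated across genes in all 6 pairs of strains (Pearson's r from 0.351 to 0.690), so the replicate number was also used as a block. The medians of log2 values were not matched any further for the comparisons reported.

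Comparisons used limma 3.58.1 in R 4.3.3. Values were taken to log2, and 1 mean per strain was fitted to all 8 arrays, which left 4 residual degrees of freedom. Tests were limma's moderated tests, two-sided, with Benjamini-Hochberg adjustment over 4940 genes for each comparison. A gene was called where its adjusted p lay below 0.05. The comparisons were each disruptant against wild type, and the arrays labelled Δpka1 against Δcgs1. With slide as a block, 3 residual degrees of freedom were left. With 2 arrays per strain, the number of arrays limits the precision. In the fit reported, the p-values measure the spread between these separate cultures, each on its own array, together with the slide difference. The 2 arrays of a strain lie on different slides. The median SE of a log2 fold change was 0.143 in that fit and 0.0589 with slide as a block. A gene not called in the fit reported may therefore still differ between strains within each slide.

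The lowest signals cannot be told from background. The 4 signals of disrupted genes that read as deleted and the signals of ura4 in the strains without it set a background limit of 2497, the highest signal of a deleted gene. This limit was chosen after the data were seen. Where a gene lay at or below it on both arrays of a strain, its fold is given as "at least", from the limit. At the other end, 370 genes (7.49%) had a mean within 10% of the highest value on the arrays, where folds are compressed.

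The comparisons, the tests, the gene lists, the rule for naming genes and most alternatives were set before the data were examined. The rule named, per comparison, the targeted and marker genes (pka1, cgs1, ppt1, ura4, leu1 and SPBC3F6.01c). It then named the 10 largest rises and 10 largest falls among called genes with a symbol whose arrays did not overlap between strains, and up to 4 called members of each list with the largest change. For a list with none called, its 2 largest values could be given without a call.

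There were 23 gene lists, written from general knowledge: PKA and glucose signalling, glucose-repressed carbon metabolism, glycolysis and ethanol fermentation, mating and pheromone response, P-cell-specific genes, M-cell-specific genes, meiosis and sporulation, core environmental stress response, heat shock chaperones, redox defence, sulfur assimilation and sulfide oxidation, coenzyme Q biosynthesis, respiratory chain and ATP synthase, tricarboxylic acid cycle, iron acquisition, phosphate starvation, cell surface adhesins and cell wall, nitrogen starvation and amino acid uptake, arginine and lysine biosynthesis, ribosome biogenesis, cytosolic ribosomal proteins, Tf2 retrotransposons, and cell cycle, mitosis and septation. Lists of at least 5 measured genes, 21 in all, were tested with camera in limma, with a preset correlation of 0.01 between genes and again with an estimated correlation. The estimate rests on the few residual degrees of freedom, and without the block its residuals hold the slide difference. What the test can detect with an estimated correlation was not simulated. A list not called by it is therefore not shown to be unshifted. Adjustment was over the 21 lists of a comparison. The P-cell list (4 genes) and the Tf2 list (1 gene) were too small for this test. Members were also adjusted over the list alone.

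The fit was tested on simulated data with 2 arrays per strain, slide shifts as seen here and 200 changed genes per draw. Without the block it recovered 14.1% of changes of 0.5, 88.4% of changes of 1 and 100% of changes of 2 on the log2 scale, with a mean of 0.1 false calls in 10 draws. With the block it recovered 95.4%, 99.4% and 100%, with a mean of 10 false calls. The list test, at an unadjusted p below 0.05, called the raised list in 20 of 20 draws and the unchanged list in 0. Apart from the slide shifts, the simulated genes varied independently of each other. These draws therefore cannot show how the list test behaves where genes are correlated.

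Alternatives were slide as a block, quantile and cyclic loess normalization between arrays, the series value table, leaving out the dimmest 25% of genes, an offset of 64 before log2, a variance trend and a robust variance model, the arrays of the compared strains alone, a minimum fold of 2, an estimated correlation between genes, and leaving out each array in turn. Added after the data were seen were quantile normalization together with the block, both normalizations before the list test, the estimated correlation with the block, the lists without the targeted and marker genes, the sulfur list without str3, the wild-type arrays split between 2 disruptants, the gene order without the targeted and marker genes, and leaving out genes at or below the background limit in both strains compared. Fold changes of a pair of disruptants share the 2 wild-type arrays, so their covariance was set against 100 simulated data sets with no change. The correlation in these sets is given beside it. Figures were drawn with matplotlib 3.10.9.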

Results

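Transcript levels of 4940 genes were measured in 4 fission yeast strains, with 2 arrays per strain. The strains were the wild type PR110 and disruptants of pka1, cgs1 and ppt1, all of mating type h+. The gene pka1 encodes the catalytic subunit of cAMP-dependent protein kinase (PKA), and cgs1 encodes the regulatory subunit that holds it inactive. By its probes, the ppt1 of this series is SPAC56F8.04c, which encodes the p-hydroxybenzoate polyprenyltransferase of coenzyme Q synthesis. Replicates of a strain correlated with r = 0.994 in wild type, 0.993 in the arrays labelled Δpka1, 0.994 in Δcgs1 and 0.991 in Δppt1, across genes, which are not independent replicates. The highest correlation with an array of another strain was 0.931 for the arrays labelled Δpka1, 0.978 for Δppt1 and 0.991 for Δcgs1 and wild type. The random-sequence control read from 821 to 1268. Log2 fold changes are given with their standard error (SE), each from 2 arrays per strain.

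The targeted genes were read first, in every array. Signal for cgs1 (SPAC8C9.03) was 1404 and 1360 in Δcgs1, against 20232 and 28238 in wild type, a fall of at least 9.57-fold (log2 fold change -4.11, SE 0.20, adjusted p = 0.0006). Signal for ppt1 was 2497 and 1910 in Δppt1, against 32691 and 41517 in wild type, a fall of at least 14.8-fold (-4.08, SE 0.20, adjusted p = 0.000458). SPBC3F6.01c, a protein phosphatase gene that also carries the name ppt1, read 34602 and 40542 in Δppt1 and 37235 and 42182 in wild type (-0.08, SE 0.13, adjusted p = 1). Signal for pka1 (SPBC106.10) did not show its disruption. It was 38387 and 46832 in the arrays labelled Δpka1 and 28743 and 34715 in wild type (0.42, SE 0.16, adjusted p = 0.164, and 0.00493 with slide as a block). These arrays are therefore called "the arrays labelled Δpka1" throughout, and directions drawn from them rest on that label.

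The marker gene ura4 (SPCC330.05c), which encodes an enzyme of uracil synthesis and marks the disruption of pka1 and cgs1, followed the labels. It read 1362 and 1627 in wild type and 1307 and 1000 in Δppt1, which was disrupted with another marker. In the arrays labelled Δpka1 it read 32716 and 37383, at least 14-fold higher than in wild type (4.55, SE 0.16, adjusted p = 3.53e-05). In Δcgs1 it read 39913 and 44787, at least 16.9-fold higher (4.83, SE 0.16, adjusted p = 0.000134). Against wild type, the presence of ura4 therefore cannot be told apart from the disruption of pka1 or cgs1. The comparison of the arrays labelled Δpka1 with Δcgs1 is free of this difference, since both carry ura4. Signal for leu1 was not called in any of the 3 disruptants (largest change -0.18, SE 0.11, adjusted p = 0.409, and 0.0327 with slide as a block, in the arrays labelled Δpka1). Signal for cgs1 was 46361 and 54252 in the arrays labelled Δpka1, higher than in wild type (1.07, SE 0.20, adjusted p = 0.0209).

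**Figure D1:**
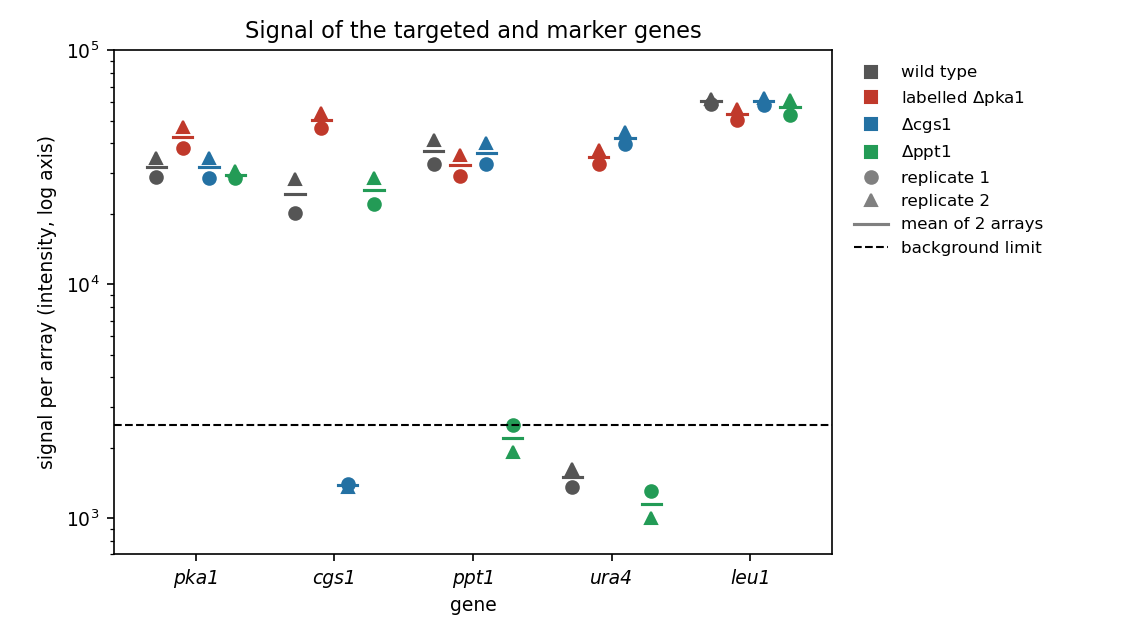
Signal of 5 genes on each of the 8 arrays (vertical axis, intensity on a log scale), by strain, with a bar at the mean of 2 arrays and a dashed line at the background limit of 2497. Signal for cgs1 and ppt1 lies at or below the line in the strain that lacks the gene, while pka1 reads 38387 and 46832 in the arrays labelled Δpka1.

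The arrays labelled Δpka1 were set against wild type to ask which transcripts depend on the catalytic subunit of PKA in growing cells. These strains differ by ura4 as well. Of the lists fixed beforehand, 9 of 15 genes that glucose normally represses, 13 of 22 genes of mating and 7 of 21 genes of the stress response rose, and 5 of 39 genes of ribosome biogenesis fell. Each list was called with a preset correlation between genes and not with an estimated one (adjusted p = 0.893 with an estimated correlation for the glucose and mating lists, adjusted p = 0.918 for the other 2). The gluconeogenic gene fbp1 (fructose-1,6-bisphosphatase) went from 8008 ± 1477 (SD, n = 2) to 62139 ± 3876 (2.97, SE 0.14, adjusted p = 6.08e-05). The regulator of meiosis mei2 went from 9331 ± 645 to 58672 ± 1247 (2.65, SE 0.18, adjusted p = 0.000263). The homocysteine synthase gene met17 went down from 53563 ± 7116 to 9515 ± 46.2 (-2.49, SE 0.13, adjusted p = 8.51e-05). In all, 418 of 4940 genes were called, 214 higher and 204 lower, and 170 of these differed at least 2-fold as measured (120 higher, 50 lower), 8 of them with a signal at background that leaves 2-fold unassured.

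Among genes with a symbol, the largest rises as measured belonged to eno102 (an enolase, at least 23.9-fold, 4.83, SE 0.16), the marker ura4, mug14 (4.30, SE 0.17), hry1 (at least 7.91-fold, 4.30, SE 0.18) and lsd90 (4.11, SE 0.17). They were followed by the α-galactosidase gene mel1 (at least 10.0-fold, 3.98), the metallothionein gene zym1 (3.83), the hexose transporter gene ght3 (at least 8.19-fold, 3.60), ddr48 (3.60) and the spore wall gene isp3 (3.47). The largest falls among them belonged to gdt1 (-3.57, SE 0.28), nrg1 (at least 6.29-fold, -3.14, SE 0.14), aes1 (-2.75, SE 0.11) and met17. They were followed by ftm1 (-1.73), ftm4 (-1.71), tlh2 (a helicase gene, at least 1.87-fold, -1.68), ftm5 (-1.67), the flocculin gene pfl3 (-1.53) and the alcohol dehydrogenase gene adh4 (-1.44). The adjusted p of these 20 genes, by limma, lay between 3.53e-05 and 0.00447. Their order is not fixed for genes at background, given as "at least", nor for eno102, mug14 and ddr48, which lay within 10% of the highest value. There folds are compressed, as for fbp1, ctt1, vht1, pho1 and arg5. Genes without a symbol, named after their values were seen, reached 4.44 (SPAC22A12.17c) and -3.48 (SPAC1039.02).

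Of 15 measured genes of glucose-repressed carbon metabolism, 9 rose and 1 fell, or 10 and 1 adjusted over the list alone. Beside fbp1 and ght3, the hexose transporter genes ght1 (2.47, SE 0.18) and ght4 (2.47, SE 0.18) rose, and adh4 was the member that fell. The list lay higher than other genes (median 0.88, camera adjusted p = 4.74e-11, and adjusted p = 0.893 with an estimated correlation). Of 20 genes of PKA and glucose signalling, 3 rose, also 3 adjusted over the list alone. They were cgs1, git5 (the β subunit of the G protein of glucose sensing, 0.97) and git3 (its receptor, 0.95), with adjusted p = 0.00367 for the list, adjusted p = 0.0255 without pka1 and cgs1, and adjusted p = 0.918 with an estimated correlation. Of 16 genes of glycolysis and ethanol fermentation, 2 rose, eno102 and the pyruvate decarboxylase gene pdc201 (2.51, SE 0.12), also adjusted over the list alone. That list was called higher on its mean of 0.49 (adjusted p = 0.0452, adjusted p = 0.918 with an estimated correlation, and 0.113 with slide as a block), although 8 of its 16 members lay above 0 and the sign of its median turned with cyclic loess normalization. Of these 16 genes, 13 lay within 10% of the highest value, where changes are compressed.

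Many, but not all, mating genes were called higher in the arrays labelled Δpka1. Of 22 measured genes of mating and pheromone response, 13 rose and 0 fell, or 15 adjusted over the list alone (median 0.72, camera adjusted p = 6.67e-11, and adjusted p = 0.893 with an estimated correlation). They included mei2, map2 (the precursor of P-factor, 2.25, SE 0.18), map1 (a regulator of P-cell genes, 1.72, SE 0.16) and rgs1 (a regulator of G protein signalling, 1.35, SE 0.20). Of the 4 P-cell-specific genes, map2 and map3 (the M-factor receptor, 0.97) rose, or 3 genes adjusted over the list alone. Of 6 M-cell-specific genes, 1 rose, mam3 (0.61), also adjusted over the list alone (list adjusted p = 0.671). The transcription factor gene ste11, which drives mating genes, rose (1.30, SE 0.18). With mei2 it made up the 2 called members of 15 genes of nitrogen starvation and amino acid uptake, also 2 adjusted over the list alone (list adjusted p = 0.117). Of 29 genes of meiosis and sporulation, isp3 rose and mcp7 fell (at least 1.40-fold, to a signal at background), with 1 rise and 0 falls adjusted over the list alone (list adjusted p = 0.671).

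Of 21 genes of the core environmental stress response, 7 rose and 0 fell, or 10 adjusted over the list alone (median 0.49, camera adjusted p = 8.21e-09, and adjusted p = 0.918 with an estimated correlation). They included zym1, the small heat shock protein gene hsp9 (2.44, SE 0.18), the nuclear envelope gene ish1 (1.96, SE 0.12) and the glutathione peroxidase gene gpx1 (1.45, SE 0.14). Among 22 redox defence genes, 4 rose, gpx1, gst3 (a glutathione transferase, 1.08), ctt1 (catalase, 0.84) and sod2 (a superoxide dismutase, 0.77), with 5 rises and 1 fall adjusted over the list alone. That list as a whole was not called (adjusted p = 0.671), and 6 of its 22 members lay above 0. In the fit with slide as a block, 5 of its members rose, 8 fell and the list pointed down (adjusted p = 0.929). Of 17 heat shock chaperone genes, 1 rose, hsp16 (1.11), also adjusted over the list alone (list adjusted p = 0.162).

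Of 39 ribosome biogenesis genes, 5 fell and 0 rose, or 6 adjusted over the list alone, and 0 of the 39 lay above 0 (median -0.35, camera adjusted p = 4.22e-07, and adjusted p = 0.918 with an estimated correlation). The largest falls among them were those of mak16 (from 13009 ± 1516 to 6474 ± 175, SD, n = 2), rpf2 (-0.88, SE 0.13), ytm1 (-0.67, SE 0.12) and dbp3 (-0.60, SE 0.10). With slide as a block, 30 of the 39 fell. Of 125 cytosolic ribosomal protein genes, 0 were called (list adjusted p = 0.172, and 0.0419, lower, with slide as a block), but 89 of the 125 lay within 10% of the highest value, where changes can be missed. Of 31 genes of the respiratory chain and ATP synthase, 0 were called, but 29 lay above 0 (median 0.16, camera adjusted p = 0.000475, and adjusted p = 0.918 with an estimated correlation), and 8 were called higher with slide as a block. None of 15 genes of the tricarboxylic acid cycle was called (list adjusted p = 0.0611, and 0.0228, higher, with slide as a block), nor any of 13 coenzyme Q genes (list adjusted p = 0.450). Adjusted over the list alone, these 4 lists had 0 calls as well, while with slide as a block 19 ribosomal protein genes fell, and 4 tricarboxylic acid cycle and 3 coenzyme Q genes rose.

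The remaining lists held called genes of both directions or few of them. Sulfur assimilation (18 genes) had met17 lower and the sulfate transporter gene sul2 higher (1.19, SE 0.13, list adjusted p = 0.671). Iron acquisition (14 genes) had the ferric reductase gene frp1 (1.32, SE 0.11) and the multicopper oxidase gene fio1 (0.72) higher and the biotin transporter gene vht1 lower (-0.46), with list adjusted p = 0.0859. Of 6 phosphate starvation genes, the acid phosphatase gene pho1 fell (-1.38, SE 0.12), or 2 genes adjusted over the list alone (list adjusted p = 0.601). Of 20 genes of adhesins and the cell wall, 4 fell, pfl3, pfl9 (-1.30), pfl8 (-1.25) and gsf2 (-0.89), and mam3 rose, with 5 falls and 1 rise adjusted over the list alone (list adjusted p = 0.318). Arginine and lysine biosynthesis (15 genes) lay lower (0 members above 0, list adjusted p = 0.0373, and adjusted p = 0.918 with an estimated correlation), with 1 call, arg5 (-0.46). In the list of cell cycle, mitosis and septation (24 genes), adg1 fell (-0.61), a call not kept adjusted over the list alone (list adjusted p = 0.671). The single measured Tf2 gene, Tf2-7, was not called (-0.25, SE 0.10, adjusted p = 0.201, and 0.00981 with slide as a block). In sulfur assimilation, iron acquisition and arginine biosynthesis, adjustment over the list alone gave the same counts.

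All 418 calls had the same sign on both slides, and with slide as a block they were kept among 1908 calls (724 higher, 1184 lower). The members that rose and fell were then 9 and 3 in PKA signalling, 6 and 4 in nitrogen starvation, 1 and 3 in meiosis, 2 and 4 in sulfur assimilation, 4 and 2 in iron acquisition and 3 and 4 in the cell cycle list. The count fell with any array of either strain left out, and the balance of directions turned with the wild-type array left out. Wild type then stood on 1 slide alone, against disruptant arrays of both, so the slide difference entered the fold changes. The median log2 fold change of all genes was -0.152 without replicate 1 of wild type, 0.0489 without its replicate 2 and -0.0416 as reported. The calls of git5, sod2, vht1 and arg5 were lost in each of the 8 fits that left out 1 array, as other calls named here were in some.

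Δcgs1 was set against wild type to ask which transcripts respond when the regulatory subunit of PKA is missing, in strains that also differ by ura4. Beyond the disrupted gene and its marker, few genes were called. The flocculin genes pfl8 (43294 ± 4081 in wild type, 20294 ± 218 in Δcgs1, SD, n = 2) and pfl9 (14718 ± 1652 and 7213 ± 12) fell, by log2 -1.09 (SE 0.11, adjusted p = 0.025 by limma) and -1.02 (SE 0.10, adjusted p = 0.025). The gene mug27 rose from 10148 ± 36.6 to 21435 ± 681 (1.08, SE 0.09, adjusted p = 0.0129). In all, 7 of 4940 genes were called, 4 higher and 3 lower, and 115 had an unadjusted p under 0.05. The other 2 called genes have no symbol and are named here after their values were seen, SPBPB2B2.18 (2.27, SE 0.21) and SPAC869.01 (at least 1.29-fold higher, 1.03, SE 0.10). By chance alone a share of 0.05 of the 4940 genes, more than these 115, would have an unadjusted p under 0.05. In simulated data this fit recovered 14.1% of changes of 0.5 on the log2 scale. Few calls in it therefore do not show that few genes changed. With slide as a block, 95.4% of such changes were recovered in draws with 200 changed genes. That fit called 41 genes in Δcgs1. This argues against as many as 200 changes of 0.5 or more, as far as the simulated spread holds. Smaller changes were not simulated.

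Other genes named by the rule were not called in Δcgs1 in the fit reported. Signal for mei2 was 3895 ± 145 in Δcgs1 (-1.26, SE 0.18, adjusted p = 0.109). The ferrichrome transporter gene str1 differed by -0.90 (SE 0.13, adjusted p = 0.113, and 0.0189 with slide as a block), and the hexose transporter gene ght5 by -0.73 (SE 0.16, adjusted p = 0.557). In the stress list, hri1 (an eIF2α kinase) differed by 0.60 (SE 0.11, adjusted p = 0.301, and 0.0105 with slide as a block). The fit with the block, unlike the one reported, also called sul2 (0.65, adjusted p = 0.0105), hsp16 (0.58, adjusted p = 0.0386) and the transporter gene tgp1 (-0.33, adjusted p = 0.0466).

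Of the 21 lists tested in Δcgs1, 5 lay lower than other genes with the preset correlation, by small amounts, each with adjusted p = 0.960 with an estimated correlation. They were respiratory chain and ATP synthase (31 genes, 0 called, median -0.07, camera adjusted p = 0.000802), iron acquisition (14 genes, 0 called, median -0.05, adjusted p = 0.000802) and cytosolic ribosomal proteins (125 genes, 89 of them near the highest value, 0 called, median -0.01, adjusted p = 0.00575). The other 2 were adhesins and the cell wall (20 genes, with pfl8 and pfl9 lower, adjusted p = 0.00827) and PKA and glucose signalling (20 genes, with cgs1 itself lower, adjusted p = 0.027). In both of these 10 of the 20 members lay above 0, with medians of 0.00 and means of -0.11 and -0.21, and the median of the second turned below 0 with either normalization. Without pka1 and cgs1, the PKA list was not called (18 genes, mean -0.00221, adjusted p = 0.492), so its call rested on the deleted gene. Adjusted over the list alone, 1 gene was lower in each of iron acquisition, PKA signalling, glucose-repressed metabolism and mating, 2 in adhesins and nitrogen starvation, and 1 was higher in each of the stress and sulfur lists. The other 16 lists had adjusted p from 0.0858 to 0.795.

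With slide as a block, Δcgs1 had 41 calls (32 higher, 9 lower), the 7 among them, and the lists of iron acquisition and adhesins (adjusted p = 0.0571 for each) and of PKA signalling (0.166) were no longer called. The calls of pfl8 and pfl9 were lost in each of the 8 fits that left out 1 array, and 2 calls were left without either array of wild type, labelled Δpka1 or of Δcgs1.

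Δppt1 was set against wild type to ask how cells without this step of coenzyme Q synthesis differ. Of the lists fixed beforehand, 6 of 14 genes of iron acquisition rose, and 3 of 31 genes of the respiratory chain and ATP synthase fell. Both lists were called with a preset correlation between genes and not with an estimated one (adjusted p = 0.608 with an estimated correlation). The transporter gene str3, which acts in haem and siderophore uptake, went from 5044 ± 1024 (SD, n = 2) to 54443 ± 2736 (3.45, SE 0.16, adjusted p = 0.000458 by limma). The cytochrome c oxidase subunit gene cox5 went down from 41369 ± 4082 to 19983 ± 1539 (-1.05, SE 0.11, adjusted p = 0.00837). In all, 50 of 4940 genes were called, 34 higher and 16 lower, and 30 of these differed at least 2-fold as measured (24 higher, 6 lower), 1 of them with a signal at background that leaves 2-fold unassured.

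Among genes with a symbol, the largest rises in Δppt1 as measured belonged to str3, the alanine racemase gene alr2 (2.88, SE 0.19), the sulfiredoxin gene srx1 (2.58, SE 0.13), the haem uptake gene shu1 (at least 4.18-fold, 2.54, SE 0.13) and osr1 (2.27, SE 0.28). They were followed by sul2 (2.25), the iron permease gene fip1 (2.08), fio1 (2.07), frp1 (1.90) and caf5 (1.56). The largest falls among them, after ppt1 itself, belonged to pfl9 (-1.75, SE 0.10), the ATPase inhibitor gene inh1 (at least 2.25-fold, -1.31, SE 0.13), the oligopeptide transporter gene isp4 (-1.28, SE 0.11) and mic26 (-1.18, SE 0.12). They were followed by cox5, mic19 (-0.99), trz2 (a tRNA processing gene, -0.98), the ATP synthase gene atp14 (-0.95) and ftm5 (-0.89). Genes mic26 and mic19 encode parts of the complex that shapes the inner mitochondrial membrane. The adjusted p of these 20 genes lay between 0.000458 and 0.0475. Their order is not fixed for genes at background, nor for fip1, fio1 and frp1, which lay within 10% of the highest value. Genes without a symbol, named after their values were seen, reached 2.49 (SPBPB2B2.08, at least 4.51-fold) and 2.26 (SPBPB10D8.02c).

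Of 14 genes of iron acquisition, 6 rose and 0 fell in Δppt1, or 9 and 1 adjusted over the list alone (median 0.83, camera adjusted p = 2.24e-16, and adjusted p = 0.608 with an estimated correlation). The members with the largest rises were str3, shu1, fip1 and fio1. Of 31 genes of the respiratory chain and ATP synthase, 3 fell, cox5, atp14 and the Rieske protein gene rip1 (-0.79, SE 0.10), or 21 adjusted over the list alone, and 0 of the 31 lay above 0. The list had a median of -0.54 (-0.56 on slide 1 and -0.55 on slide 2), with camera adjusted p = 6.92e-23, and adjusted p = 0.608 with an estimated correlation. With slide as a block, 22 members fell and 10 iron genes rose.

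Of 21 genes of the core environmental stress response, 3 rose in Δppt1, srx1, hsp9 (1.38, SE 0.18) and hri1 (1.07, SE 0.11), or 6 adjusted over the list alone (median 0.25, camera adjusted p = 6.09e-08, and adjusted p = 0.976 with an estimated correlation). Of 22 redox defence genes, srx1 and caf5, a multidrug transporter gene, rose, or 5 rises and 1 fall adjusted over the list alone (median 0.15, adjusted p = 2.12e-07, and adjusted p = 0.976 with an estimated correlation). Of the 18 genes of the sulfur list, str3 and sul2 rose, or 3 adjusted over the list alone (median 0.04, mean 0.37, adjusted p = 0.00115, and adjusted p = 0.976 with an estimated correlation). The list holds str3, an iron gene, and without it sul2 was the only call, also adjusted over the list alone (17 genes, mean 0.19, adjusted p = 0.0258, and adjusted p = 0.976 with an estimated correlation). Lists that lay lower without a called member were mating and pheromone response (22 genes, median -0.22, adjusted p = 0.000341), ribosome biogenesis (39 genes, median -0.19, adjusted p = 9.23e-05) and the tricarboxylic acid cycle (15 genes, median -0.08, adjusted p = 0.0258), each with adjusted p = 0.976 with an estimated correlation. Adjusted over the list alone, 1 mating gene, 0 ribosome biogenesis genes and 1 tricarboxylic acid cycle gene were lower. The fit with slide as a block called 16 ribosome biogenesis genes, 4 mating genes and 4 tricarboxylic acid cycle genes lower.

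Of 13 coenzyme Q genes, 1 was called in Δppt1, ppt1 itself, also adjusted over the list alone (list adjusted p = 0.335, and 0.9445 without ppt1). The α-glucosidase gene agl1 rose (0.72, SE 0.11) among 15 glucose-repressed genes, with 2 rises and 2 falls adjusted over the list alone (list adjusted p = 0.765). The Wee1-like kinase gene mik1 fell (-0.84, SE 0.13) among 24 cell cycle genes, or 2 adjusted over the list alone (list adjusted p = 0.0953). The only call among 20 adhesin genes was that of pfl9, and isp4 the only one among 15 genes of nitrogen starvation, with 1 rise and 3 falls adjusted over that list alone. The other lists tested held no called gene, or up to 2 with slide as a block. The 13 lists that were not called had adjusted p from 0.0953 to 0.939.

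All 50 calls had the same sign on both slides and were kept with slide as a block, among 636 calls (273 higher, 363 lower). The count was 13 without replicate 2 of Δppt1, 19 without replicate 1 of wild type and from 21 to 33 without any other array, and the calls of rip1, trz2, mik1 and agl1 were lost in each of these 8 fits, as other calls named here were in some.

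**Figure D2:**
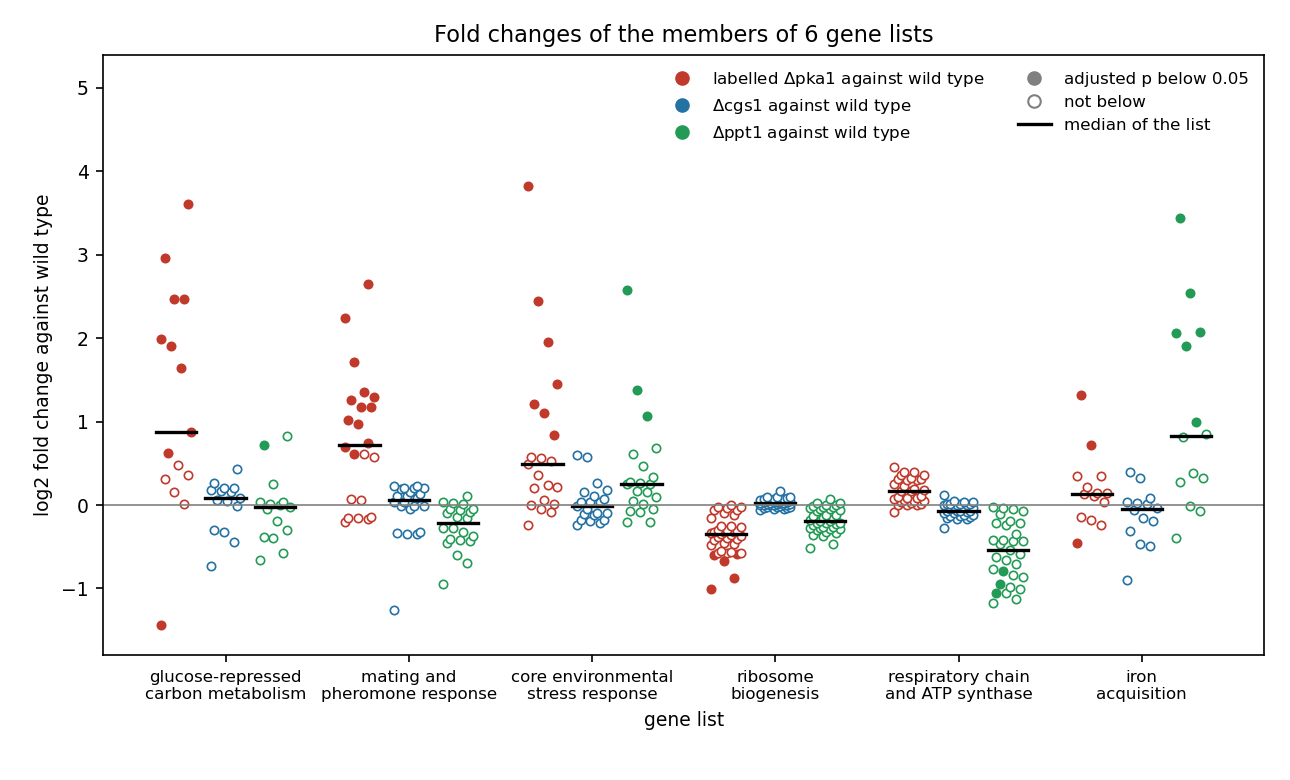
Log2 fold changes against wild type (vertical axis) of the measured members of 6 gene lists, 1 point per gene, in the arrays labelled Δpka1, Δcgs1 and Δppt1, filled where the adjusted p lay below 0.05, with a bar at the list's median. Glucose-repressed genes have a median of 0.88 in the arrays labelled Δpka1, and in Δppt1 the respiratory list lies at -0.54 and the iron list at 0.83.

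The arrays labelled Δpka1 were set against Δcgs1 because loss of the catalytic subunit and loss of its inhibitor move PKA activity in opposite directions. The targeted gene cgs1 was at least 20.1-fold higher in the arrays labelled Δpka1 (5.18, SE 0.20, adjusted p = 2.69e-05 by limma), and pka1 differed by 0.43 (SE 0.16, adjusted p = 0.152, and 0.00438 with slide as a block). Signal for mei2 was 58672 ± 1247 (SD, n = 2) against 3895 ± 145 (3.91, SE 0.18, adjusted p = 4.85e-05). The iron genes frp1 (1.38, SE 0.11), str1 (1.25, SE 0.13), fio1 (1.03, SE 0.12) and fip1 (0.69, SE 0.15) were higher in the arrays labelled Δpka1. In all, 511 of 4940 genes were called, 216 higher and 295 lower, and 188 of these differed at least 2-fold as measured (117 higher, 71 lower), 13 of them with a signal at background that leaves 2-fold unassured.

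Among genes with a symbol, the largest rises as measured, after cgs1, belonged to eno102 (at least 23.9-fold, 4.94), mug14 (4.50), hry1 (at least 7.91-fold, 4.24), lsd90 (4.18), mel1 (at least 10.0-fold, 4.05), ght3 (at least 8.19-fold, 4.05), zym1 (3.95), mei2 and ddr48 (3.53). The largest falls among them belonged to gdt1 (-3.63), aes1 (-2.84), nrg1 (at least 4.51-fold, -2.66), met17 (-2.49), ftm1 (-2.12), ftm4 (-2.06), ftm5 (-1.95), pfl3 (-1.70), adh4 (-1.70) and the pyruvate decarboxylase gene pdc102 (at least 1.43-fold, -1.63). Their order is limited as above, and genes without a symbol, named after their values were seen, reached 4.51 (SPAC22A12.17c, at least 20.7-fold) and -3.54 (SPBPB2B2.18, at least 7.68-fold). Of the 511 genes, 371 were also called in the arrays labelled Δpka1 against wild type and 3 in Δcgs1 against wild type.

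Of the 21 lists, 9 lay higher and 1 lower in the arrays labelled Δpka1 than in Δcgs1 with the preset correlation. With an estimated correlation none of the 10 was called, with adjusted p = 0.924 for the glucose and mating lists, adjusted p = 0.938 for the stress, respiratory, PKA, iron, glycolysis and ribosome biogenesis lists, and adjusted p = 0.968 for the other 2. Higher were glucose-repressed metabolism (9 of 15 genes up, 1 down, adjusted p = 2.61e-11), mating (12 of 22 up, adjusted p = 1.29e-10), the stress response (7 of 21 up, adjusted p = 3.10e-08) and the respiratory list (2 of 31 up, adjusted p = 1.53e-06). In the last, atp14 (0.53, SE 0.12) and the cytochrome bc1 gene qcr10 (0.43, SE 0.10) were the members called. Also higher were PKA signalling (2 of 20 up, cgs1 and git3, adjusted p = 0.0002, and 0.00577 without pka1 and the deleted cgs1), iron acquisition (4 of 14 up and 1 down, adjusted p = 0.00936), glycolysis (2 of 16 up, 7 of 16 above 0, adjusted p = 0.0217), nitrogen starvation (3 of 15 up, with gdh2, a glutamate dehydrogenase gene, at 1.13, adjusted p = 0.0454, and 0.105 with slide as a block) and the tricarboxylic acid cycle (0 of 15 called, adjusted p = 0.0454). Ribosome biogenesis lay lower (6 of 39 down, adjusted p = 1.58e-06). Adjusted over the list alone, 9 glucose-repressed genes, 14 mating genes, 10 stress genes, 3 PKA signalling genes and 5 iron genes were higher, 0 of the respiratory genes, and 10 ribosome biogenesis genes were lower.

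With slide as a block there were 2041 calls (619 higher, 1422 lower), the 511 among them, and the lists of heat shock chaperones (higher) and of arginine and lysine biosynthesis (lower) were also called, at adjusted p = 0.0352 for each. The count was 201 (135 higher, 66 lower) and 214 (119 and 95) without replicates 2 and 1 of Δcgs1, and 210 (120 and 90) and 241 (151 and 90) without replicates 2 and 1 labelled Δpka1, so the excess of lower genes turned in each of these fits. The calls of atp14, qcr10 and fip1 were each lost in 6 of the 8 fits that left out 1 array, as other calls named here were in some.

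**Figure D3:**
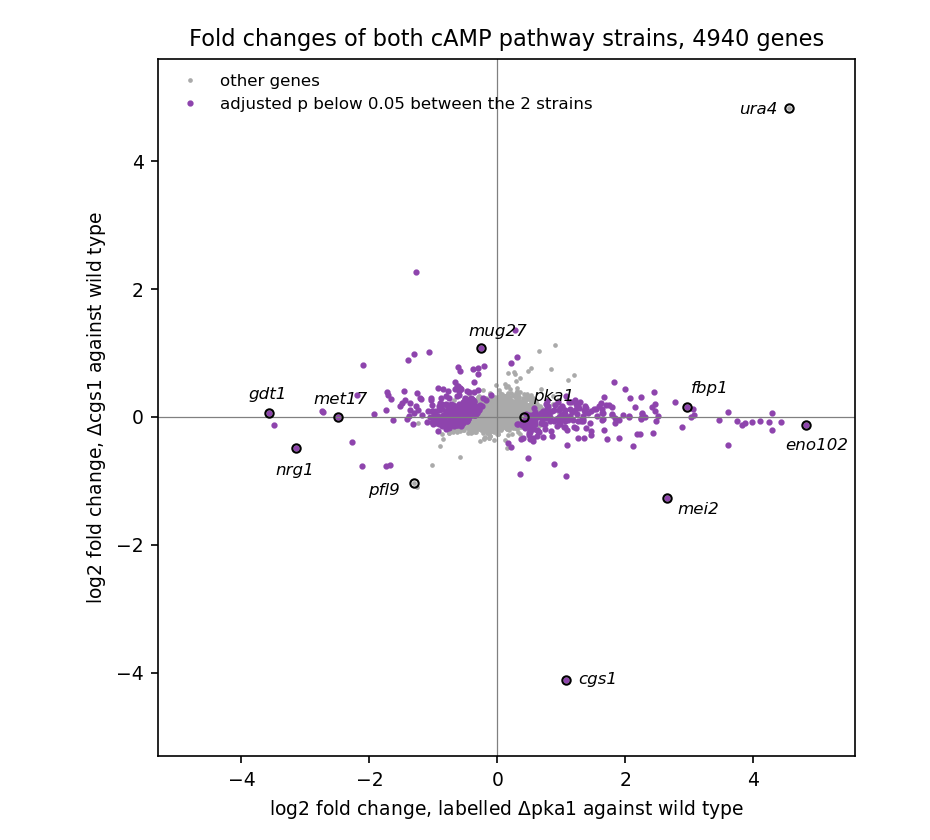
Log2 fold changes of 4940 genes against wild type in the arrays labelled Δpka1 (horizontal axis) and in Δcgs1 (vertical axis), 1 point per gene, coloured where the adjusted p between these strains lay below 0.05. The points spread along the horizontal axis (r = 0.0539), with mei2 at 2.65 and -1.26.

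Across the 4940 genes, which are not independent replicates, the fold changes of the arrays labelled Δpka1 and of Δcgs1 correlated with r = 0.0539, or 0.00927 without the targeted and marker genes. Both sets share the wild-type arrays, and simulated sets with no change gave a mean r of 0.499 (0.469 to 0.537) from that alone. Changed genes widen the spread of fold changes and so lower the part of r that shared arrays give. The observed SD was 0.468 in the arrays labelled Δpka1 and 0.163 in Δcgs1. The simulated r is therefore no yardstick for the observed r, and the covariances are compared instead. The covariance was 0.00411 against a simulated mean of 0.00282, and 0.000583 without the targeted and marker genes. Called in both were ura4 and SPAC869.01 (higher, the latter at background in wild type), pfl8 and pfl9 (lower), and, in opposite directions, cgs1 and SPBPB2B2.18, where independent calls would give 0.173, 0.124 and, for the opposite pairings, 0.130 and 0.165 genes. Part of the shared calls may come from the shared arrays, or from ura4, which both disruptants carry and wild type lacks. With the wild-type arrays split, 1 to each disruptant within its own slide, a check chosen after seeing the data, r was 0.00048 and 0.0129 in the 2 ways to split them. Without the targeted and marker genes, r in these ways lay below 0, at -0.0484 and -0.0345. In such a fit with slide as a block, ura4 was higher in both strains in each way, and pfl8 and pfl9 were lower in both in 1 of the 2.

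The fold changes of the arrays labelled Δpka1 and of Δppt1 correlated with r = 0.136 across genes, with a covariance of 0.0164 against 0.00283 from the simulated shared controls. With the wild-type arrays split in the same way, r was 0.0685 and 0.143, with a covariance of 0.00906 and 0.0182. Of the genes called in both, 12 were higher in both and 3 lower in both, where independent calls would give 1.47 and 0.661. Split in this way, with slide as a block, 50 were higher in both, 76 lower in both and 65 opposite in 1 way (independent calls would give 12.8, 38.4 and 49.9), and 54, 18 and 38 in the other (10.6, 15.9 and 31.8). The 15 without the split included hsp9, sul2, frp1, fio1, agl1 and rtc3 (higher) and pfl9, ftm5 and ymc1 (lower). Genes called in opposite directions were inh1 (0.75 and -1.31) and mic19 (0.49 and -0.99), higher in the arrays labelled Δpka1, and nrg1 (-3.14 and 1.25), SPBPB2B2.05 (at least 2.35-fold, -2.27, and 1.59) and SPCC4B3.06c (-0.87 and 0.92), lower there, against 0.693 and 1.40 from independent calls. Genes rtc3, ymc1, SPBPB2B2.05 and SPCC4B3.06c were named after their values were seen. The fold changes of Δcgs1 and Δppt1 correlated with r = 0.0196, with mug27 higher and pfl9 lower in both. The simulated mean of 0.501, from sets with no change, is no yardstick for it, for the reason given above. Their covariance was 0.000823, against 0.00283 from the simulated shared controls. When the wild-type arrays were split, r was -0.0549 and -0.0643. In those fits, with slide as a block, pfl9 was lower in both in 1 of the 2 ways and mug27 was called in both in neither. The shared wild-type arrays limit these counts in the same way.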

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

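The direction of no called gene named by the rule turned under any alternative. Only quantile and cyclic loess normalization could have turned one, since the arrays of these genes did not overlap between strains. The other alternatives keep the order of a gene's values, so they could not test its direction. Of 136 results of such genes, all calls were kept with slide as a block, with quantile or cyclic loess normalization and with the offset. A robust variance model kept 135 and a variance trend 133. Without the dimmest 25% of genes 71 of the 80 still tested were kept, with the arrays of the compared strains alone 108, and with 1 array left out between 98 and 116. An array left alone in its strain is assumed to vary like the others. It also stands for its strain on 1 slide alone, so the slide difference enters the fold changes of these fits. Counts are given in the order labelled Δpka1, Δcgs1 and Δppt1 against wild type, then labelled Δpka1 against Δcgs1 (418, 7, 50 and 511 as reported). They were 1908, 41, 636 and 2041 with slide as a block, which leaves the fold changes as they are and takes the slide difference out of the spread. They were 1809, 69, 698 and 1844 with quantile normalization, and 1733, 63, 642 and 1734 with cyclic loess. With both quantile normalization and the block, chosen after seeing the data, they were 2286, 116, 1176 and 2319. The median of all genes stayed within 0.1 of that reported in these fits. The share of higher genes among those called in Δppt1 was 68.0% as reported, 46.1% with quantile normalization, 49.2% with cyclic loess and 42.9% with the block, and in the arrays labelled Δpka1 it was 51.2%, 43.5%, 52.2% and 38.0%. The cause was not tested. Without the dimmest 25% of genes the counts were 202, 1, 18 and 235. With a variance trend Δcgs1 had 15 and Δppt1 86. With only the 4 arrays compared, so that fewer arrays set the spread, the counts against wild type were 236, 3 and 24. A minimum fold of 2 left 170 for those labelled Δpka1, 30 for Δppt1 and 188 for labelled Δpka1 against Δcgs1 by its construction, and the limit on background, chosen after seeing the data, left every count within 1.5 times.

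The fold change of pka1 in the arrays labelled Δpka1 came past the threshold with the block (0.42), quantile normalization (0.43), both (0.43) and cyclic loess (0.48), with adjusted p from 0.000515 to 0.00493. That of ura4 in Δppt1, below the background limit in both strains, did so with quantile normalization (-0.21, adjusted p = 0.0441) and with the block added (-0.21, adjusted p = 0.0346). With the wild-type arrays split between 2 disruptants, chosen after seeing the data, the correlation was 0.0685 (labelled Δpka1 and Δppt1) and, for Δcgs1 and Δppt1, -0.0549 and -0.0643, turning sign. Without the targeted and marker genes 8, 4, 8 and 10 lists were called, and without str3 in the sulfur list 8, 5, 8 and 10. The correlation of fold changes without the dimmest 25% of genes was 0.197 for labelled Δpka1 and Δppt1 and 0.0844 for Δcgs1 and Δppt1. With an estimated correlation, with or without the block, 0 lists were called in each comparison (8, 5, 8 and 10 as reported). The 5 lists of Δcgs1 became 2 with the block, 3 without the dimmest 25% of genes, 2 with quantile normalization, 1 with cyclic loess and 1 with quantile normalization and the block, the last 3 chosen after seeing the data. The cause was not tested. With slide as a block, 36 of the 98 results of genes named by the rule that had no call were called.

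With 1 array left out, the counts ranged from 181 to 387 (labelled Δpka1), 2 to 6 (Δcgs1), 13 to 33 (Δppt1) and 201 to 592 (labelled Δpka1 against Δcgs1). The lowest were reached without replicate 2 labelled Δpka1, without any array of wild type, labelled Δpka1 or of Δcgs1, without replicate 2 of Δppt1 and without replicate 2 of Δcgs1. Fold changes ranged from 0.28 to 0.57 for pka1, -4.35 to -3.87 for cgs1 in its disruptant, -4.27 to -3.88 for ppt1, and, for ura4, 4.43 to 4.68 (labelled Δpka1), 4.70 to 4.96 (Δcgs1) and -0.57 to -0.19 (Δppt1). Correlations ranged from 0.0213 to 0.115 (labelled Δpka1 and Δcgs1), 0.10 to 0.168 (labelled Δpka1 and Δppt1) and -0.0188 to 0.134 (Δcgs1 and Δppt1), the last turning sign without replicate 2 of Δppt1. Lists called ranged from 6 to 9, 0 to 7, 7 to 8 and 7 to 10, with 0 in Δcgs1 without replicate 1 of wild type. The list of cytosolic ribosomal proteins in Δcgs1 then turned direction (adjusted p = 0.557, against 1.60e-10 without replicate 2 of wild type). Against wild type, the calls of glycolysis (0.339 without replicate 2 of wild type) and of arginine and lysine biosynthesis (0.176 without its replicate 1) in the arrays labelled Δpka1, and of the tricarboxylic acid cycle in Δppt1 (0.253 without replicate 1 of wild type) were lost, as were, between labelled Δpka1 and Δcgs1, those of glycolysis (0.140) and the tricarboxylic acid cycle (0.169) without replicate 1 labelled Δpka1 and of nitrogen starvation (0.105). The calls of glucose-repressed metabolism, mating, the stress response and ribosome biogenesis in the arrays labelled Δpka1, and of the respiratory chain, iron acquisition, stress and redox lists in Δppt1, were kept without any 1 array. Signals at or below 2497, which 82 genes showed on every array, bear no fold, so the values of ura4 in Δppt1 are differences between background signals.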

Other observations

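All tests in this part were chosen only after the results were seen. Symbols that share a stem, with at least 8 measured genes, gave 74 groups, which were tested with camera as the lists were. They are called families here, although a shared stem need not mean related genes. Families such as ght, utp, nop, rrp, dbp, atp, cox and pfl share members with the lists above, so they are no independent support for them. The calls below hold with the preset correlation alone, and with an estimated correlation no family was called (adjusted p = 0.983, 0.999 and 0.992 in the arrays labelled Δpka1, Δcgs1 and Δppt1). In the arrays labelled Δpka1 the families shared that 1 adjusted p, so the test with an estimated correlation told none of them apart. In the arrays labelled Δpka1, genes named atg, which act in autophagy, lay higher (28 genes, 26 above 0, median 0.27, adjusted p = 1.39e-05, and adjusted p = 0.983 with an estimated correlation), and atg43 (0.92, SE 0.18), atg22 (0.86, SE 0.16) and atg4 (0.77, SE 0.12) were called. Of 8 hexose transporter genes named ght, 5 were called higher, among them ght5 (0.88) and ght7 (0.74, at least 1.45-fold), and of 12 hsp genes also 5, among them hsp3101 (2.15), hsp3102 (2.25) and hsp3103 (2.26). The 8 gid genes, of a ubiquitin ligase complex, all lay above 0 (median 0.34, adjusted p = 0.00565), and gid2 was called (0.49, SE 0.11). Genes of RNA polymerase subunits named rpc lay lower (13 genes, median -0.41, adjusted p = 0.00385), with rpc19 (-0.76), rpc10 (-0.76), rpc11 (-0.61) and rpc40 (-0.48) called. So did the rRNA processing genes named rrp (22 genes, median -0.41, adjusted p = 1.39e-05), with rrp14 (-0.94) and rrp40 (-0.86) among 4 called, and the families nop, utp, dbp and trm (adjusted p = 0.00305, 0.000429, 0.0148 and 0.000302). In Δppt1, atp genes (17 genes, median -0.54, adjusted p = 2.27e-06) and cox genes (13 genes, median -0.26, adjusted p = 0.0015) lay lower, as did the mrpl genes of the mitochondrial ribosome (30 genes, 6 above 0, median -0.16, adjusted p = 0.0161), while its mrps genes did not (8 genes, 6 above 0, median 0.04, adjusted p = 0.501). The wtf genes, which kill spores that do not inherit them, lay higher there (14 genes, 13 above 0, median 0.37, adjusted p = 0.000131), with 0 called. These medians kept their sign with quantile and cyclic loess normalization. The hsp family was called in Δppt1 as well, with hsp9 (1.38, SE 0.18) as its called member. In Δcgs1 the pfl family lay lower (8 genes, 2 above 0, adjusted p = 0.000239, and adjusted p = 0.999 with an estimated correlation), with pfl8 and pfl9 called.

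Several called genes lie in clusters or have no symbol. In the arrays labelled Δpka1 the galactose genes gal7 (1.05, SE 0.14), gal10 (1.70, SE 0.16) and gal1 (0.96, SE 0.15), with tgd1 (0.87, SE 0.17), formed a run of 4 adjacent genes called higher. A run of 7 held SPAC869.09 (at least 11.1-fold), pcm2 (at least 1.69-fold), mel1 (at least 10.0-fold), hry1 (at least 7.91-fold), sul2 (1.19), SPAC869.03c (at least 1.70-fold) and SPAC869.04, which lay near background in both strains. A run of 4 called lower held SPAC11D3.02c (-1.63), SPAC11D3.03c (at least 2.63-fold), SPAC11D3.04c (-1.02) and mfs2 (-0.66). Of the called genes, 122 have no symbol in the arrays labelled Δpka1 (72 higher, 50 lower), with SPAC22A12.17c (4.44, SE 0.19), SPCC1739.08c (4.25, SE 0.16) and SPAC1039.02 (-3.48, SE 0.10) among the largest. In Δppt1, 11 have none, all higher, with SPBPB2B2.08 (at least 4.51-fold, 2.49, SE 0.16) and SPBPB10D8.02c (2.26, SE 0.12) the largest.

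Signal for pka1 was not lower in the arrays labelled Δpka1 (0.42, SE 0.16). A wrong label within the series is argued against, since the lower of ura4 and cgs1 on these arrays lay 3.71 log2 units above the background limit, while every other strain lacks ura4 or cgs1 signal. A difference in brightness between arrays is argued against as well, since the median log2 fold change of all genes was -0.0416. A candidate explanation that stays open is that probes read a part of pka1 that the disruption left in place. The value of 0.42 could come from such a transcript, and the positions of the probes are not held here. The genotype pka1::ura4 does not say how much of pka1, if any, was removed. The neighbouring genes cut4 (0.26, SE 0.16, adjusted p = 0.435) and plg7 (0.14, SE 0.21, adjusted p = 0.814) were not called. A culture of another genotype from outside the series was not tested.

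Genes called in the arrays labelled Δpka1 lie next to each other more often than placed genes did, with 43 adjacent pairs in the same direction (25 higher, 18 lower) against a mean of 17.4 and a highest of 34 in 10000 random placements of 414 genes. A pair with ura4, whose signal comes from the marker and not from its own place, is among them, and without the targeted and marker genes there were 42 (24 higher, 18 lower) against a mean of 17.2 and a highest of 37, with permutation p = 1e-04 again. This permutation p of 1e-04, the smallest these placements can give, argues against chance placement, while pairs in opposite directions (21, mean 17.4, permutation p = 0.211) did not stand out. Of 32 genes in pairs that fell, 20 lay above the background limit on an array, which argues against a lost segment for these genes, and 12 lay at or below it on both, for which loss of the segment may hold and cannot be told apart from low expression. Probes shared between like copies stay open, as 1 pair shared a symbol stem and the probe sequences are not held here. A biological difference of the strain stays open beside these and was not tested. Such neighbours were not particular to the arrays labelled Δpka1. In Δppt1, 4 adjacent pairs were called in the same direction, all higher, with shu1 and str3, and fip1 and fio1 among them. Random placements gave a mean of 0.263 and a highest of 3 there (permutation p = 1e-04).

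The lower respiratory chain and ATP synthase genes of Δppt1 (median -0.54) were set against 3 explanations. A fall of all genes for mitochondrial proteins by the same amount is argued against, since 38 mitochondrial ribosomal protein genes had a median of -0.11 with 0 called, 0.43 from the respiratory list (difference -0.43, two-sided permutation p = 3e-05). A smaller fall shared with some of them is not excluded, since 30 mrpl genes lay lower (median -0.16, adjusted p = 0.0161, and adjusted p = 0.992 with an estimated correlation), although the other 8, the mrps genes, had a median of 0.04. Nor was a fall particular to the respiratory list. The mitochondrial genes inh1 (-1.31), mic26 (-1.18) and mic19 (-0.99), picked as large falls, lay lower too. How many other genes for mitochondrial proteins fell was not counted. A difference that depends on brightness is argued against, since the lowest median of 10000 random lists of the same brightness was -0.0900. Larger falls of the subunits that carry iron or haem were not seen. At the same brightness, 5 of them lay 0.0662 above the other 26, a smaller fall (two-sided exact permutation p = 0.692). Their median was -0.42 against -0.60 for the others. With so few members the test cannot decide, and this explanation stays open. The tests of these 3 explanations permute or draw genes, which are not independent replicates, so they do not measure the spread between cultures. The loss of ppt1, which the design names, stays open as well and was not tested.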
